A study of Mus musculus with 4 samples.

How the data were processed

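eCLIP libraries were made from J1 mouse embryonic stem cells after ultraviolet crosslinking, with an antibody against eIF4A2 for the IP libraries, per the labels' protocols. There were 2 IP and 2 input libraries, and the labels number the replicates 1 and 2 in each group. Per the submitters' processing notes, cutadapt 1.18, STAR 2.6.1b and the genome build mm9 were used. The peak caller, any filter on significance and the way in which replicates were combined are not given in the sources used here. The deposited list was 1 file for all 4 libraries, with chromosome, start, end, name, log2 fold and strand for each peak. The log2 values were calculated by the authors as IP over input, and none of the deposited log2 values was at or below 1, which is a fold of 2. The scale was read from the values and the file, since no header states it.

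The list holds no counts, p-values or values per library. A new test of IP against input, an estimate of the replicate error, a paired fit and the depth per sample could therefore not be had, and the precision of a single peak's fold is unknown. Intervals given for shares of peaks (Wilson or exact) and for peaks per Mb (exact Poisson), all at 95%, cover counting error over peaks only.

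The annotation at hand was for GRCm38. On 8 of the 22 chromosomes the last peak lay beyond the last GRCm38 gene, by as much as 7.13 Mb on chromosome 7. Peaks were not placed on that annotation, and no coordinates were converted. Analyses that need an mm9 annotation or sequence were not run: transcript regions, positions along mRNAs, genes with a peak, gene lists fixed beforehand and sequence composition. From the GRCm38 annotation (GENCODE M21), only the number of protein-coding genes and their merged exon length on each whole chromosome were used, in the closing section.

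Peaks were sorted by chromosome, strand and position, and starts were changed to count from 1. A stretch is a chain of peaks on one strand in which each peak starts within 1000 bases of the end of those before it. Stretches at 200, 10000 and 50000 bases were also formed. Clustering was tested against 1000 uniform placements of each peak on its own chromosome and strand, up to the last peak end, with a one-sided p. Opposite-strand neighbours were compared with 100 such placements. The median fold of a named stretch was compared with 100000 random sets of as many peaks. The correlation of width and fold was tested with 100000 permutations. The strand share was tested with an exact two-sided binomial test. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

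Features were named by a rule fixed beforehand. In the absence of gene names, it took the 10 peaks with the highest fold, the 5 stretches with the most peaks, and the chromosomes with the highest and lowest density. The rule's limit of 3 on −log10 p, and its peaks with the highest −log10 p, could not be applied. The peaks on chromosome Y and the mitochondrial chromosome, the chromosomes next in density, and the features of the closing section were chosen after their values were seen.

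The alternatives listed before the data were examined were a log2 fold of at least 3 (or 2 for the stringent count), leaving out the mitochondrial chromosome, merging peaks within 50 bases (keeping the highest fold), a minimum width of 20 bases, and other distances. The procedures were tested on simulated data with the real number of 47777 peaks. Uniformly placed peaks gave a clustering share at percentile 50 of the placements. A simulated correlation of 0.1 returned a rho of 0.091. For the 3402 stretches used for the 5′ to 3′ comparison, shuffled folds gave a difference of -0.008 (sign permutation p = 0.539), and an added shift of 0.2 returned 0.192. Ratios of simulated counts returned their scaling constant with an error of 0 to 6 decimals.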

Results

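The binding of eIF4A2 to RNA was profiled by eCLIP in J1 mouse embryonic stem cells, a line of the 129S4/SvJae strain grown without feeder cells in medium with serum and leukemia inhibitory factor. eIF4A2 is a DEAD-box RNA helicase of the eIF4A family and a close paralog of the translation initiation factor eIF4A1. In eCLIP, ultraviolet light links proteins to the RNA they touch in living cells, an antibody recovers the protein with its RNA (IP), and a sample of the same lysate taken before recovery (input) gives the background. The series held 4 libraries, 2 IP and 2 input, described as biological replicates. The question of the design was which RNA positions were enriched in the IP over the input. The measurements were deposited as 1 list of enriched intervals (peaks) for all 4 libraries, with a log2 fold of IP over input for each peak, calculated by the authors. The list gives no separate values for each library. The spread between replicates and the sequencing depth of each library are therefore unknown, and no error can be given for any peak's fold. Positions are in mm9, counted from 1. The transcripts under the peaks were not analysed here, because no mm9 annotation was at hand.

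The list placed eIF4A2 peaks on 22 chromosomes, including the mitochondrial chromosome, and most peaks were short and moderately enriched. It held 47777 peaks, and together they covered 1706 kb. The median peak was 32 bases wide, with an interquartile range of 19 to 47 bases and a maximum of 275 bases. The median log2 fold was 1.65, a 3.15-fold enrichment, with an interquartile range of 1.29 to 2.07 and a maximum of 5.63. All values lay above a log2 fold of 1 (2-fold), as in a list cut at that fold. The median and quartiles of the fold therefore describe peaks beyond 2-fold and not all bound positions. Peaks on the same strand never overlapped, although 1834 pairs of neighbouring peaks touched end to end.

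Strong enrichment was restricted to a small part of the list. A log2 fold of at least 2 (4-fold) was reached by 13537 peaks, or 28.3% (Wilson 95% interval 27.9 to 28.7%). A log2 fold of at least 3 (8-fold) was reached by 1924 peaks, or 4.03% (3.85 to 4.21%). At a log2 fold of 4 (16-fold) 145 peaks remained, and at 5 (32-fold) 11 peaks remained. These intervals cover counting error over peaks only, and the error of each fold is unknown. Many of the highest folds may rest on very few input reads, as described among the additional observations. The list carried no p-value, so the 8-fold limit was applied without the limit on significance that had been planned with it.

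**Figure D1:**
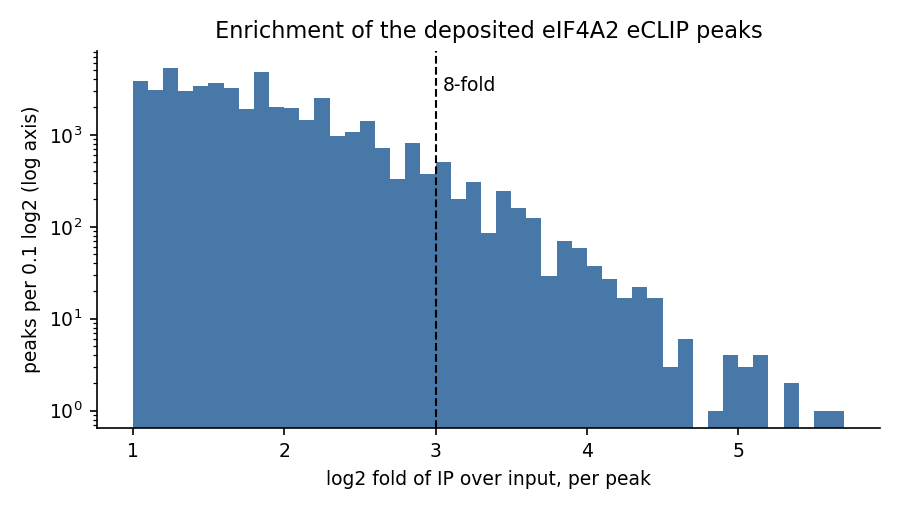
Histogram of the authors' log2 fold of IP over input for the 47777 peaks, in steps of 0.1, with the number of peaks on a log axis; the dashed line marks a log2 fold of 3. Peaks concentrate near the lower end, the median is 1.65, and 1924 peaks lie at or beyond the dashed line.

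The 10 peaks with the highest fold lay on 7 chromosomes, 5 of them on the plus strand, and were 25 to 60 bases wide. The most enriched pair of peaks lay in the same stretch of chromosome 12 on the plus strand. One covered positions 112302498 to 112302553 with a log2 fold of 5.63 (49.6-fold), and the other covered 112303121 to 112303175 with a log2 fold of 5.56 (47.2-fold). A peak on the plus strand of chromosome 17 at 34048820 to 34048869 followed with a log2 fold of 5.37. The minus strand of chromosome 7 held a peak at 34981426 to 34981459 with a log2 fold of 5.33. The same log2 fold of 5.19 was given for a peak on chromosome 9 at 57104054 to 57104108 and for one on chromosome 17 at 15623318 to 15623362, both on the minus strand. A log2 fold of 5.15 was given for a plus-strand peak on chromosome 10 at 79689561 to 79689600 and for a minus-strand peak on chromosome 4 at 140155986 to 140156045. The last 2 of the 10 had a log2 fold of 5.1. They lay on the plus strand of chromosome 5 at 72655407 to 72655460 and on the minus strand of chromosome 4 at 144744665 to 144744689. The stretch of chromosome 4 around the latter held 12 peaks, that of the chromosome 12 pair held 8, and 3 of the 10 peaks had no other peak within 1000 bases on their strand. All of these 10 values were whole-number multiples of one constant, as described among the additional observations.

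eIF4A2 peaks were concentrated in short stretches of one strand. The next peak on the same strand lay within 1000 bases for 33.9% of peaks, against a mean of 1.07% when every peak was placed uniformly on its own chromosome and strand (range 0.906 to 1.23% in 1000 placements). The one-sided permutation p was 0.001, the smallest that 1000 placements can give. Within 200 bases the share was 20.3% against 0.245%, and within 10000 bases it was 62.7% against 9.84%, each with a permutation p of 0.001. Uniform placement includes parts of the chromosome that carry no genes, so these ratios compare the list with the whole chromosome and not with the transcribed part.

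**Figure D2:**
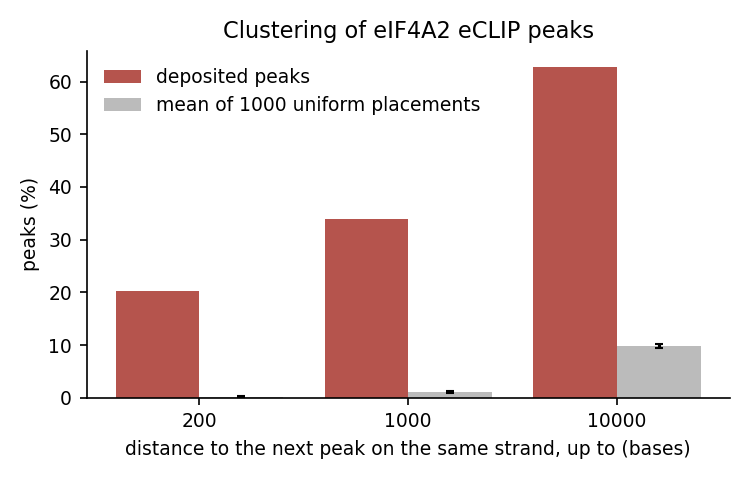
Percent of peaks whose next peak on the same strand lies within 200, 1000 or 10000 bases, for the deposited list (red) and for 1000 uniform placements (grey, mean, with bars from the lowest to the highest placement). The deposited list is higher at every distance, 33.9% against 1.07% at 1000 bases.

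The concentration was specific to the strand. Counting neighbours on either side, 49.7% of peaks had another peak within 1000 bases on their own strand and 1.72% had one on the opposite strand. The opposite-strand share was below the mean of 2.12% over 100 uniform placements. No list for the input or for another protein was compared, so whether this is particular to eIF4A2 was not tested. Only 16 peaks, or 0.0335% (Wilson 95% interval 0.0206 to 0.0544%), shared at least 1 base with a peak on the other strand. Over the whole list, 24063 peaks lay on the plus strand and 23714 on the minus strand. The plus strand held 50.37% (exact 95% interval 49.92 to 50.81%; exact two-sided binomial p = 0.11). Counting each stretch of peaks within 10000 bases once, the share was 50.85% (exact binomial p = 0.025), and among peaks at 8-fold or more it was 48.23% (exact binomial p = 0.13). These tests treat peaks or stretches as independent, although peaks were clustered.

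Joining peaks up to 1000 bases apart on one strand gave 31595 stretches, of which 24017 (76%) held a single peak. Another 172 stretches held 10 or more peaks, and they contained 4.95% of all peaks. The 5 stretches with the most peaks were all on the plus strand. The first lay on chromosome 11 at 117867071 to 117878144 (11.1 kb) and held 47 peaks with a median log2 fold of 1.74 (interquartile range 1.43 to 2.01). The stretch on chromosome 10 at 80602808 to 80612873 (10.1 kb) held 36 peaks with a median of 2.06 (1.73 to 2.49). The one on chromosome 17 at 23952395 to 23958425 (6.03 kb) also held 36 peaks, with a median of 1.45 (1.2 to 1.65) and no peak above 1.97. Merging peaks within 50 bases left 22 peaks in the chromosome 17 stretch, the fewest of the 5. On chromosome 8, 34 peaks at 123077232 to 123086483 (9.25 kb) had a median of 2.32 (1.89 to 2.77). On chromosome 4, 32 peaks at 140258062 to 140266319 (8.26 kb) had a median of 1.52 (1.32 to 1.93), although one of them reached 3.58.

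Of these 5 stretches, those on chromosomes 8 and 10 had a median log2 fold above that of random sets of as many peaks from the list. The two-sided permutation p, adjusted by the Benjamini-Hochberg method over the 5 stretches, was 0.0001 for the chromosome 8 stretch and 0.0035 for the chromosome 10 stretch. The adjusted permutation p was 0.49 for chromosome 11, 0.32 for chromosome 4 and 0.12 for chromosome 17. Folds of neighbouring peaks were correlated, so these p-values, which treat peaks as independent, are too small. Few peaks in these stretches reached 8-fold, namely 1 on chromosome 11, 0 on chromosome 10, 0 on chromosome 17, 3 on chromosome 8 and 1 on chromosome 4.

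**Figure D3:**
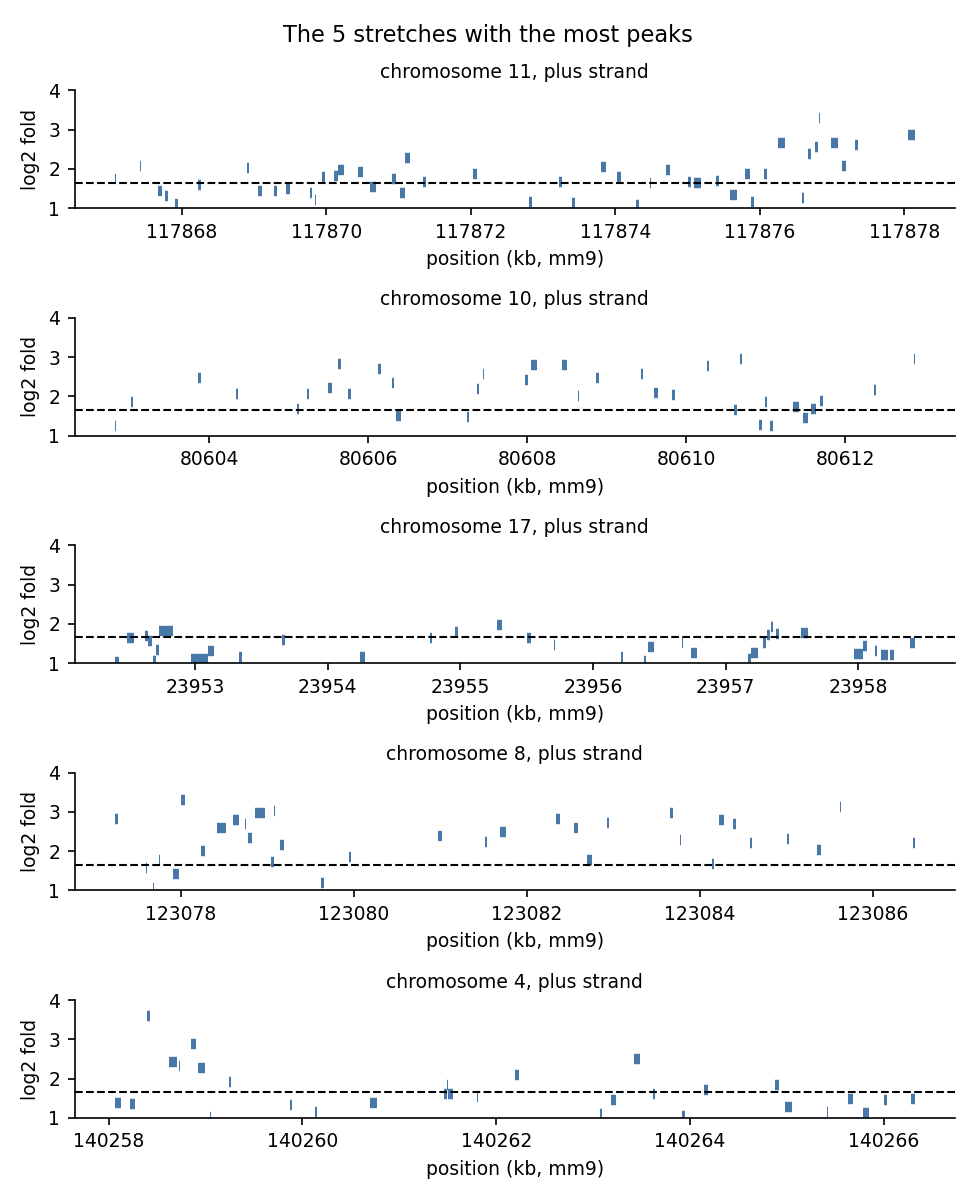
Position (kb, mm9) and log2 fold of each peak in the 5 stretches with the most peaks, with bars as wide as the peaks; the dashed line is the median of the list, 1.65. Most peaks on chromosomes 8 and 10 lie above the line, with medians of 2.32 and 2.06, and those on chromosome 17 lie mostly below it, with a median of 1.45.

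Peak density differed between chromosomes, with chromosome 11 the densest and chromosome X the sparsest of the 20 chromosomes compared. Lengths were taken as the last peak end on each chromosome. Chromosome 11 held 4176 peaks, or 34.3 per Mb (exact Poisson 95% interval 33.2 to 35.3), which was 1.89 times the mean of 18.1 per Mb. Chromosome 8 followed with 28.9 per Mb (28 to 29.9) and chromosome 17 with 25.8 per Mb (24.8 to 26.9). Chromosome X held 986 peaks, or 5.92 per Mb (5.56 to 6.31), which was 0.326 times the mean. The interval lay above the mean on 10 chromosomes and below it on 9, and only that of chromosome 10 included it. The intervals cover counting error and treat peaks as independent, which their clustering makes too narrow. The fold itself hardly differed, with chromosome medians between 1.59 and 1.7 on the log2 scale.

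**Figure D4:**
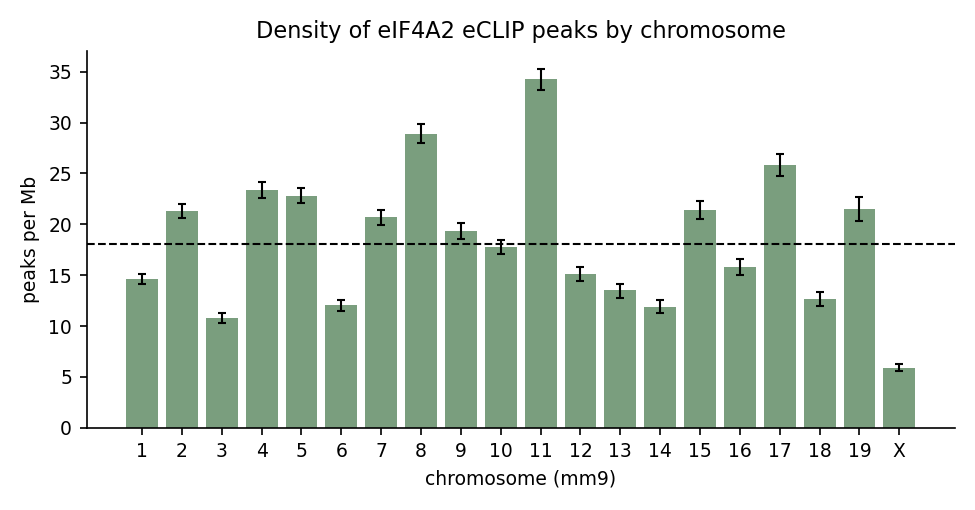
Peaks per Mb on chromosomes 1 to 19 and X, with exact Poisson 95% intervals; the dashed line is the mean of 18.1 per Mb. Chromosome 11 is highest at 34.3 per Mb and chromosome X lowest at 5.92 per Mb.

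The mitochondrial chromosome and chromosome Y contributed few peaks. The mitochondrial chromosome held 7, 4 on the plus strand and 3 on the minus strand. Its most enriched peaks were a neighbouring pair on the plus strand, at 11628 to 11669 with a log2 fold of 2.32 and at 11705 to 11737 with a log2 fold of 2.02. Its remaining peaks had log2 folds of 1.26 to 1.64. Chromosome Y held 6 peaks, which ended at position 557018, and the highest of their log2 folds was 2.24. Because the last peak lay so near the start of chromosome Y and the mitochondrial chromosome is so short, no density was compared for them.

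Enrichment hardly varied with peak width. The Spearman correlation of peak width with log2 fold was 0.04 across the 47777 peaks (permutation p = 1e-05, the smallest that 100000 resamples can give). Peaks are not independent replicates, so this p describes the list. With peaks split into 4 groups of similar size by width, the median log2 fold was 1.65 in the narrowest group (1 to 19 bases) and 1.7 in the widest (48 to 275 bases). The share of peaks at 8-fold or more was 4.02% in the narrowest group and 3.84% in the widest. Peaks at 8-fold or more and the remaining peaks had the same median width of 32 bases.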

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

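Of 45 alternative values, 31 kept their direction and their side of the threshold, or stayed within the set range. Requiring a log2 fold of at least 3 left 1924 of the 47777 peaks, and a log2 fold of at least 2 raised the stringent count from 1924 to 13537. The same limit of 3 moved chromosome 11 from 1.89 to 2.13 times the mean density (190 peaks) and chromosome X from 0.326 to 0.222 times (27 peaks). It turned the plus-strand share from 50.37% to 48.23%, neither of which differed from 50% (exact binomial p = 0.11 and 0.13). Counting each stretch of peaks within 10000 bases once gave a plus-strand share of 50.85%, which passed the test (exact binomial p = 0.025); this setting was chosen after seeing the data. Clustering within 1000 bases was 27.4% with peaks merged within 50 bases and 11.8% at a log2 fold of at least 3, each with a permutation p of 0.001. A setting also chosen after seeing the data sought a neighbour on the opposite strand, on either side, and gave 1.72%, not above uniform placement; counted in the same way, the same-strand share was 49.7%. The difference in fold between the 5′ and 3′ ends of stretches is described among the other observations. It turned from 0.094 (3402 stretches) to -0.006 (523 stretches, sign permutation p = 0.82) among peaks with a log2 fold of at least 2. That limit acts on the compared value itself, so it does not tell whether the difference is confined to lower folds. Leaving out the mitochondrial chromosome and a minimum width of 20 bases were each run for the number of peaks, the plus-strand share and the correlation of width and fold. The former was also run for the stringent count and the latter for the peaks in the 5 named stretches. Neither changed a call there, but leaving out the mitochondrial chromosome removed only 7 peaks and could hardly have done so. The minimum width left 35810 of the 47777 peaks, and 25 of the 32 peaks in the chromosome 4 stretch. Counts that fell this far were still within the set range, so an unchanged call does not mean an unchanged count. The list held no unplaced sequences. Alternatives on −log10 p were not run, because the list has no p-values. No paired analysis was possible because the deposited list has no values per library, and for the same reason no replicate could be left out. The depth of the libraries is unknown, so what it limits could not be measured.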

Other observations

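The tests of the recurring fold values against whole-number ratios, of random order within stretches, of gene number per chromosome and of strand by chromosome were chosen only after the result was seen, as were the features named in this part. Among the 172 stretches of 10 or more peaks, the median log2 fold ranged from 1.13 to 3.66. The most enriched lay on the minus strand of chromosome 11 at 69484505 to 69485752. Its 21 peaks covered 82.7% of 1.25 kb, with a median log2 fold of 3.66 (interquartile range 3 to 3.87), or 12.6-fold. The next were on the minus strand of chromosome 11 at 117827769 to 117830454, with 15 peaks and a median of 3.01, and on the plus strand of chromosome 19 at 45089831 to 45093431, with 12 peaks and a median of 2.93. The least enriched was on the minus strand of chromosome 14 at 55262832 to 55264581, with 11 peaks and a median of 1.13. At a joining distance of 200 bases, the stretch with the most peaks was on the plus strand of chromosome 1 at 88423514 to 88425212, with 31 peaks and a median of 2.51. At 10000 bases it was on the plus strand of chromosome 8 at 123012062 to 123116331, with 175 peaks over 104 kb and a median of 2.2.

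Neighbouring peaks on one strand had similar folds. Spearman's rho across pairs was 0.37 for gaps up to 200 bases (9696 pairs), 0.25 for larger gaps up to 1000 bases, 0.13 for those beyond that up to 10000 bases and 0.07 for those beyond that up to 50000 bases, each with a permutation p of 0.0005, the smallest that the resamples can give. It was 0.01 for gaps over 50000 bases (8297 pairs, permutation p = 0.16). The hypothesis that folds are shared along a strand predicted a difference of over 0.1 in rho between gaps up to 1000 bases and gaps over 50000 bases, and the difference was 0.3. That prediction restates the fall of rho with distance. Only pairs on the same strand were compared, so it cannot tell sharing along a strand from nearness on the chromosome. The pairs with gaps up to 200 bases include the 1834 pairs that touched end to end. Pairs are not independent replicates. Whether the shared unit is a transcript was not tested.

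The fold values recurred: the 47777 peaks held 2739 distinct values, and the 5 most frequent accounted for 27.4% of peaks. After subtracting one constant, 0.24 on the log2 scale, 75.6% of the values were log2 ratios of whole numbers with a denominator up to 10 (relative tolerance 1e-07), and 99.96% with a denominator up to 200, against at most 0.00209% with denominators up to 10 for 100 other constants. The commonest ratios were 2 to 1 (4301 peaks), 3 to 1 (3878) and 4 to 1 (2006), which is consistent with each fold being a ratio of whole read counts from 1 IP and 1 input count, scaled by 1 constant. Means of the log2 folds of 2 replicate pairs would give square roots of simple ratios, which (with denominators up to 10 before the root) were found at 0.0% of peaks, so the values argue against such averaging; pooled libraries or a single pair stay open. All 10 peaks with the highest fold, and 68.2% of the 1924 peaks at 8-fold or more, were at whole-number ratios, against 27.8% of the list, so a candidate explanation is that many of the highest folds rest on very few input reads, but a reduced ratio does not give the counts themselves.

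Folds were slightly lower at the 3′ end of stretches, taking the strand in the list as that of the RNA. In 3402 stretches of at least 4 peaks joined at 10000 bases, the 5′-most peak exceeded the 3′-most by 0.094 ± 0.013 (SE) on the log2 scale (means 1.77 and 1.68), and it was higher in 1849 stretches and lower in 1475 (two-sided sign permutation p = 1e-05, the smallest that the resamples can give). The 3′-most peak differed from the mean of the interior peaks of its stretch by -0.094 ± 0.010 (SE; sign permutation p = 1e-05), whereas the 5′-most peak differed from it by 0.001 ± 0.010 (SE; sign permutation p = 0.94), a comparison added after the profile along the stretches was seen. The 5′-most peaks were also wider, by 11.07 ± 0.56 bases (SE). After regression of fold on width, the difference between the ends was still 0.089. On the plus and minus strands it was 0.087 and 0.102. These values argue against peak width and a trend along the chromosome as the whole cause. Without the peaks at the simplest ratios the difference was 0.122 (1711 stretches). The ratio sets the fold, so leaving out such peaks acts on the compared value and does not decide on coarse folds. At a joining distance of 1000 bases the difference was 0.042 (sign permutation p = 0.013). Among peaks with a log2 fold of at least 2 it was -0.006 ± 0.027 (SE, 523 stretches), so no difference was seen there. Because that limit acts on the compared value itself, it does not tell whether the difference is confined to lower folds. A stretch is not a transcript, and uneven input coverage was not tested and stays open, as no coverage was at hand.

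Peaks per chromosome rose with the number of protein-coding genes over 20 chromosomes (Spearman rho = 0.81, permutation p = 4e-05; Pearson r = 0.76, permutation p = 0.00014), also without chromosomes 2 and 7, the farthest from the median gene number (rho = 0.78, permutation p = 0.0003; r = 0.79, permutation p = 7e-05). Chromosome 8 had the most peaks per gene, 3.65, against a median of 2.24 and 2.83 on chromosome 12, the next highest. Chromosome X, the sparsest per Mb, was also the lowest of the 20 per gene, at 1.04. Chromosome 11, the densest per Mb, had 2.55 peaks per gene. Chromosome 8 stayed the highest without the 10 densest stretches of each chromosome (3.09 against 2.5 on chromosome 5). It was also the highest per kb of protein-coding exons (0.857 against 0.693 on chromosome 4). These values argue against the 10 densest stretches or a longer exonic length as the whole cause. Joined at 10000 bases, its peaks numbered 3.78 per stretch against at most 3.09 on the others of the 20 chromosomes. Its stretches per gene were 0.964, against 1.14 on chromosome 12, 1 on chromosome 5 and 0.982 on chromosome 18. Counted by stretches, chromosome 8 was therefore not the highest, and its lead lay in the number of peaks per stretch. Beyond 110 Mb, in 16.2% of its length, lay 37.8% of the peaks of chromosome 8. Higher transcript abundance from chromosome 8, as an extra copy could give, was not tested and stays open, and no biological explanation could be tested with these groups.

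Chromosome 8 also carried more peaks on the plus strand, 59% of 3796 (exact binomial, adjusted p = 1.6e-27 over 22 chromosomes), and by peaks 12 of the 22 chromosomes passed the test, 7 towards the plus strand and the others towards the minus strand, such as chromosome 15 with 44.9% (exact binomial, adjusted p = 1.7e-05). Counting stretches, none of those towards the minus strand passed, and chromosome 15 had 48.6% of 716 (exact binomial, adjusted p = 0.81). On chromosome 8 the plus strand held 54.7% of the 1003 stretches at 10000 bases (exact binomial, adjusted p = 0.027). Counting stretches, 2 other chromosomes passed the same exact test, both towards the plus strand: chromosome 12 with 59.9% of 733 (adjusted p = 2.1e-06) and chromosome 18 with 56.5% of 504 (adjusted p = 0.027). The test by peaks treats clustered peaks as independent, so its p-values are too small. Many stretches also lay near each other, since joining at 50000 bases gave 8341 stretches in place of 17797. The p-values by stretches may therefore be too small as well.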
